A study of Caenorhabditis elegans with 52 samples.

How the data were processed

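Whole young adult hermaphrodites of 3 genotypes were collected untreated or after 1 to 18 h in 1 mL of S medium with OP50 bacteria and either U0126, at 100 uM, or DMSO, per the labels. RNA was extracted with Trizol, and polyA RNA was made into libraries with a TruSeq kit, per the labels' protocols. One table of counts per library, 52 in all, was deposited by the authors, with raw read counts per gene that had not been normalized. CASAVA, TopHat, DESeq and the ce10 build are named in the submitters' processing notes, and their versions, the counting tool and the annotation are not given in the sources used here.

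The tables listed 45461 gene IDs, of which 44936 were matched to names in an Ensembl WBcel235 annotation, used for names only, and 525 were not matched and kept under their IDs. Each table ended in 5 lines of unassigned categories, which were left out of library sizes and tests. In 51 libraries these lines were filled in, with 48.2 to 54.8 percent of reads outside any gene and 0.31 to 0.45 percent ambiguous. They were blank in the library PL U0126 2 h replicate 2. Whether the counting took account of strand is not given in the sources used here. With this kit a strand-specific setting would leave a large part of the reads outside genes, so the counts could hold only part of each gene's reads, and this stays open. Because the kit does not mark the strand, counts of overlapping and antisense genes are uncertain, as are those of near-identical copies such as the major sperm protein genes. Depth was 9.36 to 25.6 (in units of 1e6 counts assigned to genes) in N2, 5.66 to 35.12 in PL and 5.37 to 16.0 in PF, and the median number of genes detected per library was 17833, 18290 and 16657.5.

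Groups were formed from genotype, treatment and hour. All 52 libraries were fitted together with 1 coefficient per group (29 groups, 23 residual degrees of freedom). Genes with a CPM of at least 1 in at least 2 libraries were kept (16462), scaled with TMM and tested with edgeR 4.0.16 (trended dispersion, quasi-likelihood fit not robust, quasi-likelihood F test), run in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 3 comparisons averaged over 1, 2, 4 and 6 h, which include the PF groups of 1 library, were fitted on their own libraries with the hour as a factor: PF drug over 13893 genes, PL against PF in DMSO over 14998 and the difference of drug responses over 15441. There were 23 comparisons, plus that of PL with N2 in DMSO at 2 h. Standard errors are the log2 fold change divided by the square root of F. A gene with no counts in 1 group has its fold change given as at least N-fold, against a floor of 3 counts over the group, with no fitted value.

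The genes named were chosen by a rule: the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups (no such condition for differences of responses), the 4 members with the smallest adjusted p of each list named, and 10 regulators (puf-8, lip-1, fbf-1, fog-1, fog-3, fem-3, tra-2, gld-1, mpk-1 and rme-2). Results of some genes that the rule picks are not reported here. The 28 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Of 644 list tests 227 passed with the preset correlation, 12 with an estimated correlation and 115 with fry. The 12 were the P450 genes (N2 at 2 h, and PL at 1, 2 and 4 h), the glucuronosyltransferases (N2 at 2 h, and PL at 2 and 4 h), the chaperones (PL against PF untreated, and PL in DMSO at 1 h against untreated), the intestine and somatic gonad genes (PL against N2 untreated), and the intestine genes in the difference of drug responses at 18 h. The lists, comparisons, tests, naming rule and first set of alternatives were chosen before the data were examined. Alternatives added after seeing the data were the fit without N2 untreated replicate 2, the DMSO 2 h comparison, a robust fit, the fit of the 6 PL 1 h libraries alone, a crossed pairing in N2 at 6 h, and PL against PF in DMSO without PL DMSO 1 h replicates 1 and 2.

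Replicates were checked by correlation and by a chi-square per degree of freedom, whose lowest value over pairs of replicates was 2.63, so no library in these 25 pairs was a copy of its partner, and tables of different groups were not compared this way. N2 untreated replicate 2 raised the common dispersion to 0.129, from 0.063 without it. Whether replicate numbers pair libraries was checked by correlating deviations from the group means. Only PL at 1 h had 3 pairs. There same-numbered U0126 and DMSO libraries correlated at 0.806 to 0.907 across genes and other-numbered ones at up to 0.756. Replicates 1 and 2 were alike, at r of 0.992 in DMSO and 0.986 in U0126, and replicate 3 stood apart in both groups. The check therefore sets replicate 3 apart and does not decide whether the numbers 1 and 2 are pairs. Adding the pairing as a replicate block did not move the count at that hour by more than 1.5 times.

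The alternatives of that first set were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, a fit of fewer or more libraries, a replicate block, leaving out each library and leaving out the third replicates. The tests were also run on simulated data with 200 changed genes, in the library sizes of the real groups and with 1 pooled spread per gene. No group was given its own spread. The rates below therefore need not hold where replicates agreed less, as in untreated N2 and PL at 1 h. With edgeR, 4-fold changes were called for 75 to 89 percent of changed genes in the simulated comparisons within the 52-library fit that had no difference of responses, and 2-fold changes for 32 to 45 percent. For differences of responses at 2 h and 18 h, 55 and 68 percent of 4-fold changes were called. In PF over time 59 percent of 4-fold changes and 2 percent of 2-fold changes were called. Called genes had the right sign in 100 percent of cases, with 0 to 8 false calls by edgeR per run and 71 by DESeq2 in PF over time. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Permutation tests used 100000 resamples.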

Results

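RNA was sequenced from whole young adult Caenorhabditis elegans hermaphrodites of 3 genotypes: N2, the wild type (18 libraries), PL, which is puf-8; lip-1 (24 libraries), and PF, which is puf-8; fbf-1 (10 libraries). PUF-8 and FBF-1 are RNA-binding proteins that repress germline mRNAs, and LIP-1 is a phosphatase that dampens the RAS-ERK pathway. Loss of either pair of genes leaves hermaphrodites that make sperm in place of oocytes. The drug was U0126, which blocks MEK, the kinase that activates ERK, and the vehicle was DMSO. Worms were untreated or were kept in liquid medium with bacteria and 100 uM U0126 or DMSO for 1, 2, 4, 6 or 18 h. The question was what the drug and the genotype did to the mRNAs of germline sex, and which other genes moved with them.

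The 52 libraries fell into 29 groups, of which 19 had 2 libraries, 2 had 3 and 8 had 1. Depth was 5.37 to 35.12 (counts assigned to genes, in units of 1e6) per library. All 8 groups with 1 library were PF groups in DMSO or U0126, so those were compared over time with the hour in the model. The labels do not say whether replicates were separate cultures, so adjusted p values measure only the spread between these samples. Replicates of most groups correlated at r of 0.903 to 0.993 over 10479 genes, which are not independent of one another. The exceptions were the PL 1 h pairs, at 0.777 to 0.992, and the pair of untreated N2 libraries, at 0.283. The library labelled N2 untreated replicate 2 had sperm mRNAs that the other N2 libraries lacked, with gsp-3, a sperm phosphatase, at 721 CPM against 1.2 in replicate 1. Its rme-2, the yolk receptor of oocytes, was at 57.1 CPM against 1500. It was kept in the fit, and values without it are given wherever it moved a count by more than 1.5 times.

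The mutated genes were checked first. Mean puf-8 was 145 CPM (SD 44.5) in N2, 8.49 (SD 7.26) in PL and 6.04 (SD 2.53) in PF. Mean lip-1 was 64.5 CPM (SD 17.2) in N2, 1.97 (SD 0.946) in PL and 6.38 (SD 1.8) in PF. Mean fbf-1 was 29.7 CPM (SD 10.7) in N2, 19.3 (SD 6.84) in PL and 1.46 (SD 1.33) in PF. No PL library was above 3.72 CPM of lip-1, and no PF library was above 3.89 CPM of fbf-1. The highest puf-8 was 36.6 CPM in PL, in U0126 at 18 h, and 11.8 in PF. The lowest N2 values of puf-8, lip-1 and fbf-1 were 26.2, 11.5 and 11.3 CPM, all in the library labelled N2 untreated replicate 2. In untreated worms puf-8 was at 164 and 26.2 CPM in N2 replicates 1 and 2 and averaged 5.77 in PL and 4.02 in PF. In DMSO at 18 h puf-8 averaged 97.5 CPM in N2 and 9.59 in PL, and in U0126 at 18 h it averaged 221 and 30.1.

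**Figure D1:**
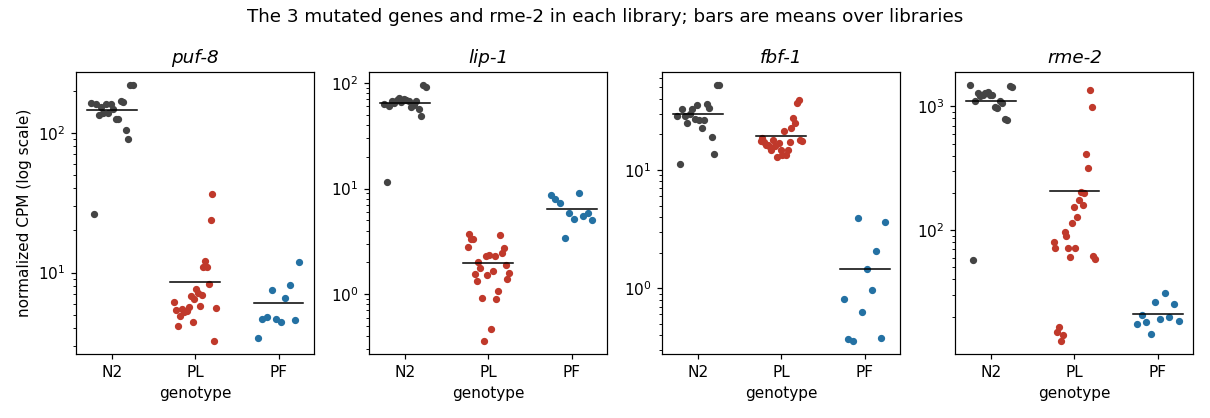
CPM of puf-8, lip-1, fbf-1 and rme-2 in each of the 52 libraries on a log axis, with bars at the mean over all libraries of each genotype. The library labelled N2 untreated replicate 2 lies below the other N2 libraries for all 4 genes.

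Untreated PL and PF worms differed in collagen and chaperone genes, among others. Their molt-gene means differed as well, at a mean log2 CPM of 3.04 in PL and 1.06 in PF. The fbf-1 mRNA itself was higher in PL, at 18.3 CPM against 0.592 (log2 fold change 4.87, SE 0.39, edgeR quasi-likelihood adjusted p = 2.48e-08). The largest rises in PL included grd-6, a hedgehog-related gene, at least 241-fold higher than in PF, C02E7.7, at least 374-fold, and the collagen col-88, at 147 CPM against 0.0934. The largest falls were nhr-74, a nuclear hormone receptor (log2 fold change -5.22, SE 0.91, edgeR adjusted p = 0.00417), D2063.1, K09C4.1, srlf-34 and T16G1.6. Of the cuticle collagens 14 of 149 rose in PL and none fell, among them col-81 (3.06) and col-139 (2.50), and 68 rose and 1 fell when adjusted over the list alone. The camera test gave the collagens adjusted p = 1.98e-19, and adjusted p = 0.112 with an estimated correlation. Chaperone genes rose in PL, with 3 of 13 called (dnj-13, hsp-43 and hsp-12.6, the last at a log2 fold change of 4.70) and 6 adjusted over the list alone (camera adjusted p = 1.71e-08, and adjusted p = 0.0114 with an estimated correlation). Their list means were 6.62 and 5.80 log2 CPM in the untreated PL libraries and 4.23 and 4.55 in untreated PF. In PL in DMSO at 1 h they were 4.57, 4.33 and 4.52. In PF in DMSO at 1 h the mean was 4.58. No PL library in DMSO or U0126 was above 4.74, which argues against a high level that the genotype holds in all conditions. In DMSO over 1 to 6 h, without PL 1 h replicates 1 and 2, the chaperone median of PL against PF was 0.02. Whether the high level belongs to untreated PL worms or only to these samples was not tested. Of 25 stress genes 3 rose (8 adjusted over the list alone): the metallothionein mtl-1 (2.68), the transferase gst-7 (1.79) and the superoxide dismutase sod-3 (2.26), with camera adjusted p = 1.86e-05, and adjusted p = 0.111 with an estimated correlation. Oocyte and sperm genes were not separated gene by gene: 0 of 36 oocyte and 0 of 43 sperm genes passed with edgeR in this comparison. Their medians were 1.09 and -0.32, with camera adjusted p = 1.44e-05 for oocyte genes, and adjusted p = 0.671 with an estimated correlation.

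In the edgeR quasi-likelihood test of untreated PL against PF, 140 genes were higher and 22 lower in PL at an adjusted p under 0.05, out of 16462 tested. Without N2 untreated replicate 2 in the fit, which widens the pooled spread, the split was 781 and 145. Any 1 of the 4 libraries compared was needed for the count: leaving out each in turn left 16 to 43 genes, lowest without PL untreated replicate 1 and highest without PF untreated replicate 2. Neither puf-8 (0.53, adjusted p = 0.759 with edgeR) nor lip-1 (-1.36, adjusted p = 0.244 with edgeR) passed.

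Oocyte genes were lower in both mutants than in N2. In untreated worms, 32 of 36 oocyte genes were lower in PL (33 adjusted over the list alone) and 34 of 36 in PF, with medians of -3.12 and -4.35. Genes of meiosis (chromosome axis, synapsis and recombination) and of DNA replication were lower as well: 28 of 29 meiosis genes in each mutant, and 29 of 30 replication genes in PL and 28 of 30 in PF. The regulator fem-3, which promotes male fate, was lower in PL (-2.90, edgeR adjusted p = 3.25e-06), and rme-2 was lower in both (-3.35 and -5.36). Genes of somatic tissue went the other way in PL. There 11 of 16 intestine genes rose, with the esterase ges-1 at 1.64 and the proton pump subunit vha-6 among them, and camera gave adjusted p = 1.13e-06, and adjusted p = 0.0421 with an estimated correlation. Of the somatic gonad genes, 9 rose and 2 fell in PL, with the secreted proteases and matrix genes gon-1 (1.73) and mig-6 (2.11) up and the gap junction gene inx-14 (-1.63) down, and the call held at adjusted p = 0.0463 with an estimated correlation. Muscle genes rose in PL for 12 of 19, and collagens for 88 of 149 with 5 lower. In whole worms a smaller germline share would raise somatic genes too, and this was not told apart from changes within the tissues. Of the mutated genes, puf-8 was lower in PL (-4.04) and PF (-4.57), lip-1 was lower in PL (-3.52, edgeR adjusted p = 1.74e-05) and also in PF (-2.16), which carries lip-1, and fbf-1 was lower in PF (0.592 CPM, edgeR adjusted p = 6.59e-09) and not called in PL (-0.13).

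Against untreated N2, the edgeR test called 2038 genes higher and 4214 lower in PL, and 1421 higher and 4247 lower in PF. When N2 untreated replicate 2 was left out, these became 5730 and 5034 for PL, and 5181 and 5046 for PF. With it left out, 42 of 43 sperm genes and 28 of 28 major sperm protein genes were higher in PL, 34 of 36 oocyte genes were lower, and the intestine and somatic gonad calls were lost (adjusted p = 0.187 and adjusted p = 0.278 with an estimated correlation). That library also decided which genes fell furthest in PL: F09C6.10, at least 8820-fold lower, clec-161, at least 2330-fold, and clec-95, at least 1720-fold, were high in it. Camera's call on the oocyte genes was lost when the correlation was estimated (adjusted p = 0.594 with an estimated correlation in PL, and adjusted p = 0.72 with an estimated correlation in PF). A fit of the 6 untreated libraries alone called 0 genes with edgeR in each of these genotype comparisons, with 511 (PL against PF), 2117 (PL against N2) and 2002 (PF against N2) at an unadjusted p under 0.05.

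PL and N2 were also compared in DMSO at 2 h, a comparison chosen after seeing the data because of that library. Sperm genes were higher in PL: 28 of 28 major sperm protein genes and 40 of 43 other sperm genes, with the major sperm protein genes at sums of 7126 and 7637 CPM in the PL libraries and 29.24 and 76.63 in N2. The male-promoting regulator fog-3 was at 20.6 CPM in PL against 0.309 in N2 (6.02, SE 0.98, edgeR adjusted p = 1.48e-05). Oocyte genes fell for 33 of 36 (median -3.56), meiosis genes for 29 of 29 (-1.75) and replication genes for 29 of 30 (-2.62). Of the RAS-ERK components and regulators 18 fell and 3 rose, with mpk-1, the ERK gene itself, at -1.95. The regulators gld-1 (-2.81), tra-2 (-1.93), fem-3 (-3.96) and rme-2 (-3.79) fell too. Somatic lists rose: 17 of 19 muscle genes, 12 of 16 intestine genes, 16 neuron genes with 1 lower, 22 immunity genes with 1 lower, and 103 collagens with 5 lower. Whole worms were sequenced, and oocyte gene sums were 5100 and 4884 CPM in PL against 24610 and 23760 in N2. A smaller germline share in PL would raise somatic genes and lower germline genes too. It was not told apart from changes within the tissues. With edgeR, 5697 genes were higher and 5190 lower. Each list's camera result here was at adjusted p = 0.422 or above with an estimated correlation. Of the mutated genes puf-8 was at -4.83 and lip-1 at -5.18, and fbf-1, which PL carries, was also lower (-0.88, edgeR adjusted p = 0.00891).

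In DMSO over 1 to 6 h, PL and PF differed in oocyte and sperm genes. Among oocyte genes 16 of 36 were higher in PL (26 higher and 1 lower adjusted over the list alone), including lin-41 (1.54), egg-4 (1.70), meg-1 and mex-3 (1.44), which act in oocyte growth, the eggshell and maternal RNA control. Among sperm genes 10 of 43 were lower (17 adjusted over the list alone), including ssp-19 (-1.85), and 6 of 28 major sperm protein genes were lower. The germline regulators gld-1 (0.72) and rme-2 (1.83, at 103 CPM against 25.2) were higher in PL, fog-3 was lower (-0.93, edgeR adjusted p = 0.0275), and the Notch receptor glp-1 was higher (0.87). Replication genes rose for 7 of 30, with the cyclin cye-1 at 0.67 and the reductase rnr-1 at 1.05. The largest differences were Y68A4A.13 (32.2 CPM against 0.264) and fbf-1 (4.85, SE 0.24, edgeR adjusted p = 7.12e-06) upward, and the acyltransferase oac-32 (-3.53) and dod-23 (-2.70) downward. The other targets differed less: lip-1 was lower in PL (-1.68, 2.17 CPM against 7.02).

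The edgeR test, over 14998 genes with hour as a factor, called 759 higher and 562 lower in PL. Replicates 1 and 2 of PL DMSO 1 h, with molt-gene means of 6.32 and 6.55, stood apart: their sperm list means were 4.22 and 4.24, against 5.58 in replicate 3 and 5.88 in PF at 1 h, and their oocyte means 3.69 and 3.82, against 5.05 in replicate 3 and 3.99 in PF. A fit without these 2 libraries, chosen after seeing the data, called 1094 higher and 986 lower, with 28 of 36 oocyte genes higher and 2 lower, 17 of 43 sperm genes lower, and 11 of 28 major sperm protein genes lower and 1 higher. Without the PF 6 h pair, the PF 4 h pair or the PF 1 h pair the total fell to 428, 627 and 830. For both oocyte genes (camera adjusted p = 2.23e-09) and sperm genes (camera adjusted p = 3.06e-10) the list call was lost, at adjusted p = 0.624 with an estimated correlation.

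PL worms in DMSO at 18 h differed from untreated PL worms. Oocyte genes rose for 30 of 36 (31 adjusted over the list alone, and 26 with relative log expression scaling), with lin-41 at 3.31, oma-2 at 3.58, trcs-1 at 2.42 and mex-3 at 2.89. The yolk receptor rme-2 went from 76.1 to 367 CPM (2.27, SE 0.80, edgeR adjusted p = 0.0439) and fem-3 from 4.74 to 17.5 CPM. Replication genes rose for 19 of 30 (20 adjusted over the list alone), cye-1 among them at 2.15, and meiosis genes for 10 of 29. Collagens fell for 77 of 149 and rose for 5, with col-81 at -7.45 and col-129 at -7.37, while molt-gene means were 3.61 and 2.47 in the untreated libraries and 1.14 and 1.05 in DMSO at 18 h (camera adjusted p = 0.14 with an estimated correlation). Also lower were 9 of 13 chaperone genes, 9 of 16 intestine genes (the phosphatase pho-1 at -3.45 and the peptide transporter pept-1 at -4.12, with 2 higher), 9 of 19 muscle genes and 9 histone genes. The chaperone fall starts from the high means of the untreated PL libraries, 6.62 and 5.80 log2 CPM, against 3.30 and 3.21 in DMSO at 18 h. Immunity genes rose for 10 and fell for 2, the caenacin cnc-2 at 6.24 and the lysozyme lys-7 at 2.98 among the rises. Of the sperm genes, the translation regulator cpb-1 (-1.21) and the transcription factor spe-44 (-2.57) fell and the others did not pass.

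The edgeR test called 2227 genes higher and 1312 lower, and with relative log expression scaling 1480 and 1690, where the direction of the split flipped. The median of all genes was 0.05 with TMM and -0.08 with the other scaling. The oocyte median was 2.44 and 2.29 under these scalings (camera adjusted p = 4.81e-12, and adjusted p = 0.431 with an estimated correlation). Leaving N2 untreated replicate 2 out of the fit gave 3949 and 2865. Leaving out each library compared gave totals from 1219 (without PL untreated replicate 2) to 2139 (without PL DMSO 18 h replicate 2), against 1418 without PL untreated replicate 1 and 1235 without PL DMSO 18 h replicate 1.

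After 1 h in DMSO, chaperones fell in PL. The stress-induced hsp-70 dropped from 67.8 to 2.07 CPM (-5.03, edgeR adjusted p = 0.00426), and 4 of 13 chaperone genes fell (10 adjusted over the list alone), with dnj-13 at -1.46, hsp-43 at -1.25 and hsp-110 at -1.04. The camera test gave adjusted p = 3.09e-10, and adjusted p = 0.00301 with an estimated correlation. This fall starts from the untreated PL libraries, whose chaperone means of 6.62 and 5.80 log2 CPM also made the difference from untreated PF. Genes of fat use rose for 5 of the fasting list and fell for 2, with acs-2 (3.12), lipl-4 (2.54) and icl-1 (1.96) up and hacd-1 (-2.79) down. Glucuronosyltransferases rose for 13 of 65 with 1 lower, and argk-1, an arginine kinase, rose from 4.06 to 66.8 CPM. By edgeR 280 genes were higher and 231 lower. The total was 1623 without N2 untreated replicate 2, 1394 without PL DMSO 1 h replicate 3, 88 and 97 without PL untreated replicates 1 and 2, and 230 and 300 without PL DMSO 1 h replicates 1 and 2. Those PL 1 h replicates 1 and 2 had molt genes at a mean log2 CPM of 5.91 or more, and the third replicates at 1.56 or less. In DMSO their yolk protein genes were at means of 9.92 and 10.69 log2 CPM, against 14.12 in replicate 3. Untreated PL libraries were at 13.89 and 13.83. How far the calls at 1 h rest on DMSO, and how far on what sets replicates 1 and 2 apart, was not tested.

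The same comparisons in N2 rested on the library labelled N2 untreated replicate 2. After 1 h in DMSO 28 of 28 major sperm protein genes, 41 of 43 other sperm genes and 8 of 8 seminal fluid and male genes fell against untreated. With that library the edgeR test called 1238 genes higher and 3794 lower, and without it 306 and 233, with 0 of the 43 sperm genes among them. The other libraries moved the count too: the total was 10689 without N2 untreated replicate 1, and 2568 and 3341 without N2 DMSO 1 h replicates 1 and 2. At 18 h in DMSO 2250 genes were higher and 3262 lower, and 1507 and 4710 with relative log expression scaling, while without that replicate 3236 and 2443 were, and without N2 untreated replicate 1 the total was 9539. Sperm and major sperm protein genes again fell for 41 of 43 and 28 of 28, for instance msd-4, at least 12000-fold lower. Neuron genes rose for 6 of 21 (medians 0.76 with TMM and 0.44 with the other scaling), with the touch-neuron tubulin mec-7 and the synaptic gene unc-10 (1.51) among them, and for 20 of 21 without N2 untreated replicate 2 (camera adjusted p = 0.00462 with an estimated correlation). Embryonic genes rose for 6 of 18 (medians 1.38 and 1.06), with the nuclear receptor nhr-25 at 4.38, molt-gene means went from 1.38 and 0.68 to 3.55 and 3.94, and ribosomal protein genes fell for 41 with 1 higher.

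U0126 induced detoxification genes in N2 within 2 h. At 2 h, 27 of 67 cytochrome P450 genes rose (36 adjusted over the list alone), with cyp-34A7 going from 0.17 to 73.0 CPM. Glucuronosyltransferases, which conjugate foreign compounds, rose for 13 of 65 (25 adjusted over the list alone), among them ugt-1 (4.41) and ugt-16 (4.48), and glutathione transferases for 4 of 41, gst-33 at 5.02. The kinase-like genes E02C12.10 (9.17) and E02C12.6 (8.03, 0.873 to 230 CPM) and the dehydrogenase gene R05D8.9 (7.81) were among the largest rises. The anion transporter oat-1 (-3.24), the lectin-domain gene clec-1 (-2.08) and B0281.3 (-2.22) were among the largest falls. Camera gave the P450 genes adjusted p = 1.9e-74, and adjusted p = 2.35e-05 with an estimated correlation, and the glucuronosyltransferases held at adjusted p = 0.0287 with an estimated correlation. With edgeR 118 genes were called, 14 of them lower, with 178 (32 lower) when N2 untreated replicate 2 was left out, and totals of 63 and 75 without replicate 1 of N2 DMSO 2 h and of N2 U0126 2 h. At 1 h it called 2 higher and 2 lower: E02C12.6 (5.78, edgeR adjusted p = 2.66e-08) and cyp-34A7 (4.15) rose, and clec-1 (-1.85) and F37B12.1 (-2.49) fell. That total was 11 without N2 untreated replicate 2, 2, 1 and 2 without N2 DMSO 1 h replicate 1, N2 DMSO 1 h replicate 2 and N2 U0126 1 h replicate 2, and 53 with DESeq2. No regulator of germline sex passed at 1 or 2 h.

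At 6 h in N2 the P450 genes cyp-35A4 (1.08 to 728 CPM, 9.39, edgeR adjusted p = 7.86e-10) and cyp-35A3 (1.74 to 956 CPM) had risen, with 16 of 67 P450 genes called upward (25 higher and 6 lower adjusted over the list alone). Of 27 fat-metabolism genes 3 fell: fasn-1, the fatty acid synthase, at -1.10, the lipase lipl-4 at -1.84 and hacd-1 at -1.64. The exchanger nhx-6 (-9.49, 22.8 to 0.0235 CPM), the pump catp-2 (-8.33) and dod-3 (-7.18) fell most. The lysozyme lys-7 (-2.22) and thn-2 (-1.74) fell while irg-6 (4.90) rose, and the intestinal enzymes pho-1 (-1.26) and cpr-1 (-1.13) fell. The meiotic axis gene him-3 rose slightly (0.54, edgeR adjusted p = 0.0465). The yolk protein genes had a median of -0.56 and none passed. At this hour edgeR called 83 genes higher and 150 lower, and with relative log expression scaling 102 and 80, which flips the split. A fit that left out N2 untreated replicate 2 called 199 and 519. Leaving out each of the 4 libraries compared gave totals of 75 (without N2 DMSO 6 h replicate 2) to 95 (without N2 U0126 6 h replicate 1), with 80 and 87 for the other pair. The P450 call was lost at adjusted p = 0.0867 with an estimated correlation.

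At 18 h in N2 genes of somatic tissues were lower with the drug and genes of meiosis and sex determination higher. Medians and counts are given with TMM first and relative log expression scaling second, because the scaling moved the median of all genes from -0.41 to 0.00. Neuron genes fell for 18 of 21 and 16 of 21 (medians -1.73 and -1.29), with mec-7 at -1.73 and unc-10 at -1.87, and 1 rose under the other scaling. Muscle genes fell for 16 of 19 and 10 of 19 (-1.63 and -1.17), tni-4, a troponin, at -2.22. Intestine genes fell for 13 of 16 and 10 of 16 (-1.24 and -0.79), with pho-1 at -2.02, cpr-1 at -1.94 and the transcription factor elt-2 at -1.66. Embryonic genes fell for 10 of 18 and 8 of 18 (-2.02 and -1.57), and hypoxia genes for 11 and 6 (-1.20 and -0.75). Collagens fell for 45 and 35 of 149 (-1.53 and -1.07), col-165 from 100 to 0.797 CPM, and molt-gene means were 3.55 and 3.94 in DMSO against 1.87 and 1.93 in U0126. Meiosis genes rose for 22 and 28 of 29 (0.87 and 1.32), with him-3 at 1.02 and syp-1 at 0.89, and sex-determination genes for 13 and 19 of 22 (0.97 and 1.42), tra-3 among them at 1.32. Of the germline stem cell list 11 and 13 of 15 rose, and of the histone genes 6 and 9 rose and 4 and 2 fell. Regulators rose as well with TMM: fbf-1 (1.67, to 52.3 CPM), puf-8 (1.18, edgeR adjusted p = 0.0202), fog-1 (1.09) and fem-3 (1.28). Oocyte genes had medians of 0.96 and 1.41, with daz-1 (1.09) up, cav-1 (-2.65) down and the others not called with TMM, and 13 of 36 up with the other scaling.

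The edgeR test called 2463 genes higher and 4955 lower at 18 h in N2 with TMM, and 4650 and 3091 with relative log expression scaling, which flips the split. Without N2 untreated replicate 2 it called 3814 and 5921, and without N2 U0126 18 h replicate 1 a total of 4705. Lists near the middle changed direction with the scaling: P450 genes had medians of -0.20 and 0.25, the organelle stress list -0.09 and 0.36, and the immediate-early list -0.36 and 0.09. The P450 genes cyp-35A4 (7.13) and cyp-35A3 (6.67) still stood high. No list of this comparison passed camera with an estimated correlation, the nearest being intestine at adjusted p = 0.195 with an estimated correlation.

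In PL, genes of detoxification rose from 1 h. E02C12.6 rose from 0.862 CPM (7.17, SE 0.38, edgeR adjusted p = 2.28e-12), and 14 of 67 P450 genes rose (30 adjusted over the list alone), cyp-33C1 at 7.51. The stress transcription factor xbp-1 fell (-0.56, 292 to 198 CPM), as did clec-1 (-1.64) and B0281.3 (-2.04). None of the immediate-early or RAS-ERK list genes passed at 1 h with edgeR, at medians of -0.24 and -0.07. At 2 h 32 of 67 P450 genes rose (40 adjusted over the list alone, median 1.90), 17 of 65 glucuronosyltransferases and 7 of 41 glutathione transferases. E02C12.10 was at least 2370-fold higher, and T26H5.9 (-3.72), ced-11, a channel-family gene (-3.65), and dod-3 (-2.85) fell. At 4 h 30 of 67 P450 genes rose, cyp-35A4 from 0.613 to 705 CPM, along with 20 of 65 glucuronosyltransferases and 5 of 41 glutathione transferases. There Y105C5A.13 (-5.62) fell, dod-3 fell from 114 to 2.59 CPM, and xbp-1 (-0.64) and the RAS regulator gap-3 (-0.92) fell. At 6 h 7 P450 genes passed, E02C12.6 stood at 130 CPM against 0.708, and T26H5.9 (-4.81) and dod-3 (-4.02) were down. No regulator of germline sex passed from 1 to 6 h in PL.

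Camera's P450 call held with an estimated correlation at 1 h (adjusted p = 0.0001 with an estimated correlation), 2 h (adjusted p = 1.54e-05 with an estimated correlation) and 4 h (adjusted p = 0.000155 with an estimated correlation), and not at 6 h (adjusted p = 0.812 with an estimated correlation). Glucuronosyltransferases held at 2 h (adjusted p = 0.0353 with an estimated correlation) and 4 h (adjusted p = 0.0240 with an estimated correlation). The edgeR test called 40 genes (4 lower) at 1 h, 157 (15 lower) at 2 h, 205 (32 lower) at 4 h and 38 (12 lower) at 6 h. With N2 untreated replicate 2 left out of the fit these were 62 (10 lower), 250 (48 lower), 340 (68 lower) and 456 (47 lower). At 1 h replicates 1 and 2 of both PL groups had molt genes at a mean log2 CPM of 5.91 or more, against 1.56 or less in the third replicates. The 1 h total was 26 without PL DMSO 1 h replicate 2 and 26 without PL U0126 1 h replicate 3. At 2 h it was 66 and 86 without PL DMSO 2 h replicates 1 and 2, 390 without PL U0126 2 h replicate 1 and 94 without PL U0126 2 h replicate 2. That last library had 17 of 28 major sperm protein genes more than 4-fold below its partner, at a sum of 2360 CPM against 7550, while 1 of 43 other sperm genes was (sums of 5980 and 4690). Its table is the only one with blank category lines, so whether it was made like the others is not known. At 4 h it was 114 and 112 without PL DMSO 4 h replicates 1 and 2 and 136 without PL U0126 4 h replicate 2. At 6 h, leaving out PL DMSO 6 h replicate 2 gave 13, and each of the other libraries (PL DMSO 6 h replicate 1, PL U0126 6 h replicates 1 and 2) gave 16.

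At 18 h of U0126 in PL, oocyte genes rose for 7 of 36 (10 adjusted over the list alone, 5 with relative log expression scaling). Camera gave them adjusted p = 3.51e-05, and adjusted p = 0.755 with an estimated correlation. Among them were egg-2 (2.10), cey-2 (2.21), oma-1 (1.51) and cey-3 (1.30), which act in the eggshell and in oocyte RNA control and maturation. Meiosis genes rose for 18 of 29 (24 adjusted over the list alone, 12 with the other scaling), including syp-2 (1.26), him-14 (1.16), prom-1 (1.35) and htp-3 (1.10), at adjusted p = 0.485 with an estimated correlation. Sex-determination genes rose for 6 of 22 and replication genes for 7 of 30, with cdk-1 at 1.19 and hcp-3 at 1.48. The regulators fog-1 (1.53, SE 0.28, 45.5 to 132 CPM, edgeR adjusted p = 0.000793), fem-3 (1.63), gld-1 (283 to 803 CPM) and mpk-1 (1.02) rose, while rme-2 (1.68, edgeR adjusted p = 0.16) and fog-3 (0.85) did not pass. The remaining mRNA of puf-8, which is mutated in PL, rose as well (1.65). Of the sperm genes cpb-1 (1.10) and spe-44 (1.20) rose. P450 genes rose for 15 and fell for 2, with cyp-35A4 from 0.0428 to 461 CPM and cyp-35A3 from 0.246 to 975 CPM. The organelle stress genes hsp-60 (1.78) and hsp-4 (0.97) rose, and the RAS-ERK list went both ways, 4 up and 5 down, with ark-1 at 1.10, lin-45, the RAF gene, at 1.11 and lin-25 at -1.08. Immunity genes fell for 5, lys-7 at -3.23, and rose for 2, irg-6 at 4.40.

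The edgeR test called 1868 genes higher and 448 lower in PL at 18 h, and 1378 and 616 with relative log expression scaling. Without N2 untreated replicate 2 it called 3428 and 1305, and leaving out each library compared gave totals of 451 (without PL U0126 18 h replicate 2), 485 (without PL DMSO 18 h replicate 2), 983 (without PL DMSO 18 h replicate 1) and 1286 (without PL U0126 18 h replicate 1). Somatic lists were little called: 1 of 19 muscle genes and 1 of 16 intestine genes fell, and 0 of 21 neuron genes passed with edgeR.

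**Figure D2:**
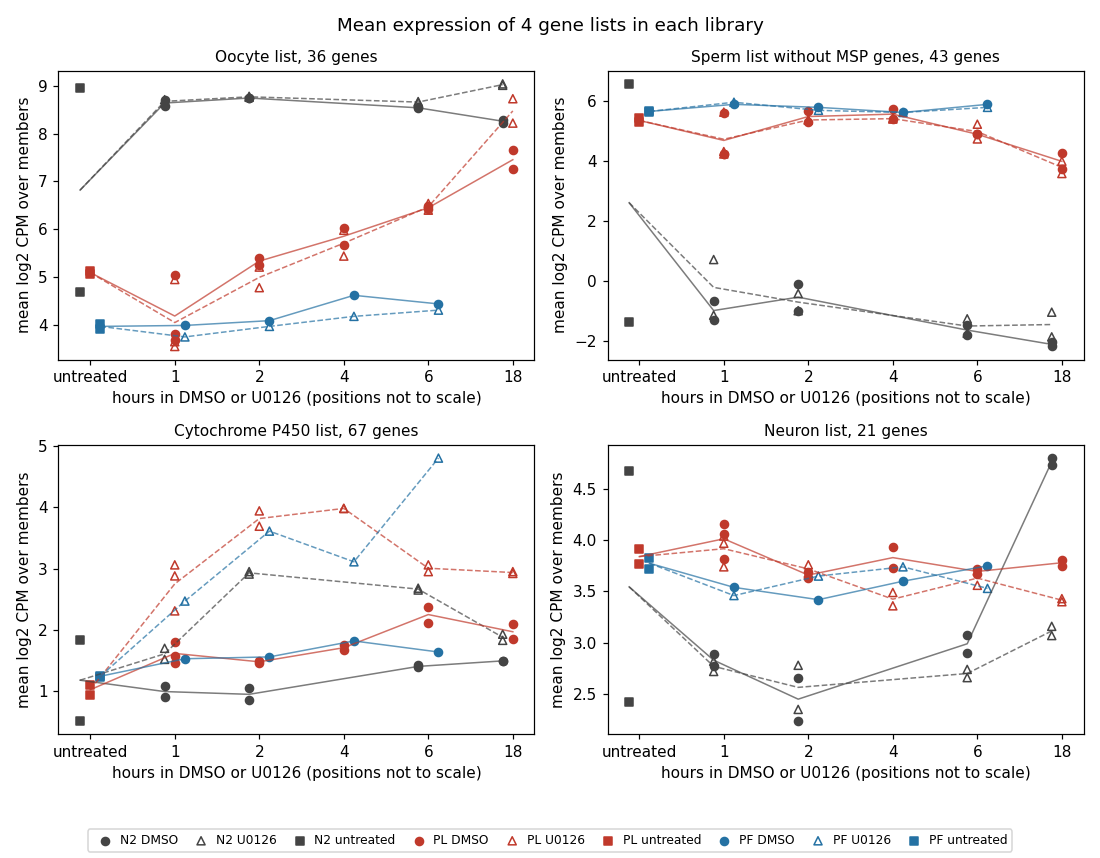
Mean log2 CPM of the oocyte, sperm, P450 and neuron lists in each library by hour, genotype and treatment. PL libraries in DMSO at 18 h had oocyte means of 7.65 and 7.26, in U0126 8.73 and 8.22, and untreated 5.12 and 5.07.

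In PF worms, genes of detoxification rose over 1 to 6 h of U0126. E02C12.10 rose from 0.407 to 414 CPM (9.86, SE 0.32, edgeR adjusted p = 2.61e-07) and cyp-35A4 from 0.463 to 501 CPM (10.18). P450 genes rose for 17 of 64 (40 higher and 2 lower adjusted over the list alone), glucuronosyltransferases for 11 of 60, and the transferases gst-44 (7.89) and gst-5 (2.76) rose. C07A4.2 (-4.12), ced-11 (-3.91), clec-7 (-2.15) and B0281.3 (-2.11) fell. None of the 10 regulators passed, fbf-1 among them (2.22, edgeR adjusted p = 0.284). In all, edgeR called 74 genes higher and 15 lower of 13893, with totals of 137, 22, 42 and 173 without the 1 h, 2 h, 4 h and 6 h pair of PF libraries. The P450 call was lost at adjusted p = 0.255 with an estimated correlation.

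Whether the drug acted differently by genotype was tested directly. At 6 h the P450 genes cyp-35B2 (-6.48) and cyp-35A5 (-3.89), the transferases gst-33 (-4.26) and ugt-1 (-2.70) and the lipid-binding lbp-8 (-3.31) rose less in PL than in N2. The PL U0126 6 h libraries stood apart from the other late hours, with P450 genes at sums of 1546 and 1723 CPM, against 7467 and 6038 at 4 h and 3916 and 5173 at 18 h. The lysosomal nuclease nuc-1 (1.29), the glucosidase aagr-2 (0.98), the hydrolase abhd-3.2 (1.93) and F28H7.3 (1.96, SE 0.23, edgeR adjusted p = 8.79e-05) had a positive difference, PL minus N2: with the drug aagr-2 went from 523 to 343 CPM in N2 and from 1200 to 1550 in PL. At 18 h cyp-35A4 (5.90) and cyp-35A3 (5.30) had a positive difference, PL minus N2. In PL, cyp-35A4 was at 0.0856 CPM or less in DMSO at 18 h, against up to 0.915 CPM untreated. The size of its difference therefore rests on a DMSO level near the floor. The difference was also positive for 7 of 16 intestine genes with TMM and 2 with relative log expression scaling (medians 1.14 and 0.61): for instance, pho-1 went from 49.6 to 12.2 CPM in N2 and from 8.5 to 14.1 in PL. Differences were 2.75 for pho-1, 1.58 for act-5 and 2.20 for ifb-2, and the list passed at adjusted p = 0.0354 with an estimated correlation. Other tissue lists moved in the N2 libraries too: neuron means went from 4.73 and 4.80 to 3.16 and 3.07 log2 CPM in N2, and from 3.81 and 3.75 to 3.40 and 3.43 in PL, and embryonic means in N2 from 2.00 and 2.13 to 0.24 and 0.27. The hypoxia genes cysl-1 (1.77) and ldh-1 (1.35) were lowered less in PL than in N2 with TMM (cysl-1 from 30.7 to 23.2 CPM in PL and from 48 to 10.6 in N2), and 0 of that list were called with the other scaling. The argonaute ppw-2 (-1.87), the protease tra-3 (-1.41) and syp-1 (-0.98) had a negative difference, for instance tra-3 from 35.6 to 88.9 CPM in N2 and from 46.7 to 44.1 in PL. The oocyte, sex-determination and P450 medians changed sign with scaling (0.24 and -0.30, 0.02 and -0.52, 0.34 and -0.17), and none of the 10 regulators passed.

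Drug response of PL minus N2 was called by edgeR for 0 genes at 1 h (175 at an unadjusted p under 0.05, 39 by DESeq2) and 0 at 2 h (233 at an unadjusted p under 0.05, 29 by DESeq2). Without PL U0126 2 h replicate 1, the 2 h total was 134, and without PL U0126 1 h replicate 2 the 1 h total was 4. At 6 h 4 genes were higher and 7 lower, 33 and 11 without N2 untreated replicate 2, and 1 to 6 in all when each library compared was left out, lowest without PL DMSO 6 h replicate 1 and highest without N2 U0126 6 h replicate 1. At 18 h 264 were higher and 24 lower with TMM, and 65 and 453 with relative log expression scaling, which flips the split (medians of all genes 0.30 and -0.23). Of the 288, 89 were called with both. The 18 h total was 1500 without N2 untreated replicate 2, and 27 to 190 when each of the 8 libraries was left out, from N2 U0126 18 h replicate 1 to PL U0126 18 h replicate 1. Against PF, the response in PL differed for 0 genes by edgeR over 1 to 6 h (842 at an unadjusted p under 0.05, 1 by DESeq2).

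**Figure D3:**
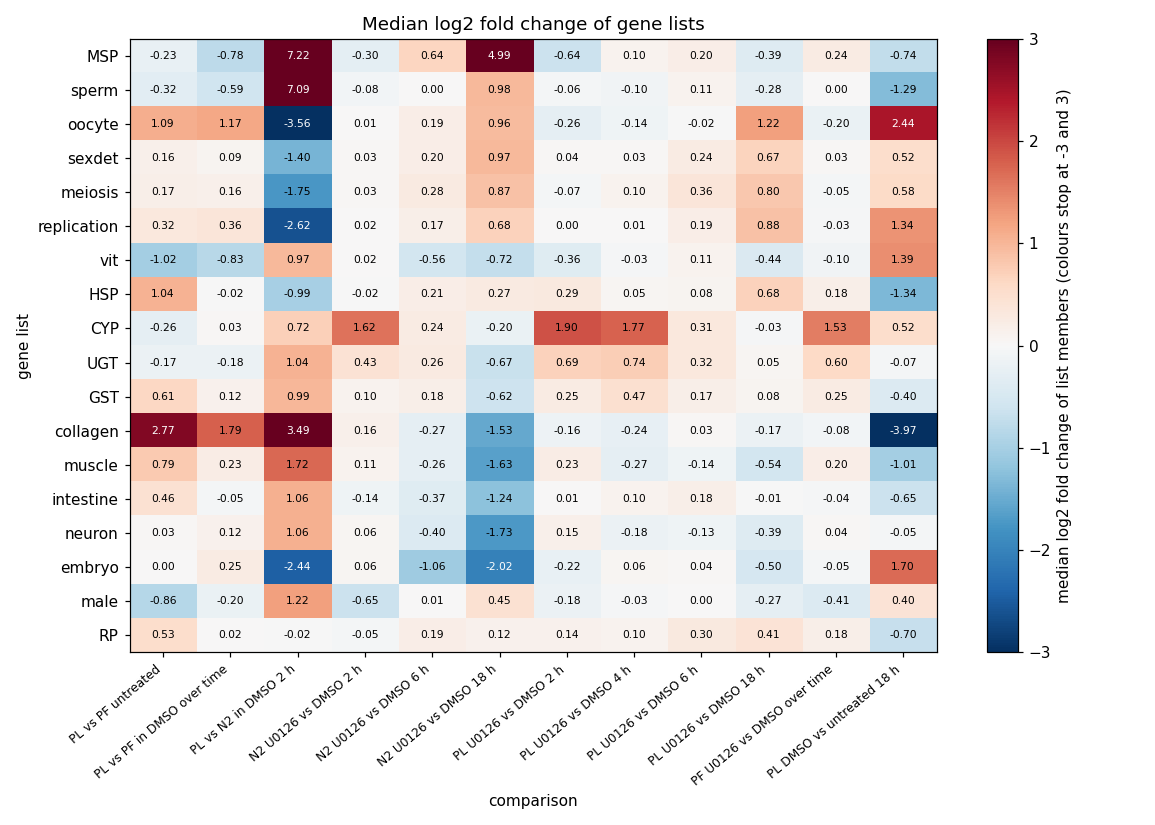
Median log2 fold change of 18 gene lists in 12 comparisons with TMM scaling. In N2 at 18 h of U0126 the P450 median is -0.20, and 0.25 with relative log expression scaling, which is not drawn.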

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

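The tests of the PL minus N2 difference, its scaling and its leaving out of libraries, the molt-gene test, the count of splits for the difference of PL and PF drug responses and the splits across hours were chosen before the data were examined or the result seen, and the other tests below, among them the count of genes called with both scalings, after the result they address was seen. For the molt-gene test, the collagen mean of that library and mlt-10 in other libraries had been seen.

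The response to U0126 differed between PL and N2 by a direct test of the difference, for 11 genes at 6 h and 288 at 18 h with edgeR at an adjusted p under 0.05. At 6 h 4 were more positive in PL and 7 less, and at 18 h 264 and 24. At 6 h the PL U0126 libraries had lower P450 sums (1546 and 1723 CPM) than at 4 h (7467 and 6038) and 18 h (3916 and 5173), and whether this lies in the genotype or in those libraries was not tested. With relative log expression scaling the 18 h split was 65 and 453, so the balance of the split rests on the scaling, and 89 genes were called with both. The 6 h count was 1 without PL DMSO 6 h replicate 1, PL U0126 6 h replicate 1 or PL U0126 6 h replicate 2, 3 without N2 DMSO 6 h replicate 1 or 2, 4 without N2 U0126 6 h replicate 2 or PL DMSO 6 h replicate 2, and 6 without N2 U0126 6 h replicate 1. The 18 h count was 36, 32, 27 and 94 without N2 DMSO 18 h replicates 1 and 2 and N2 U0126 18 h replicates 1 and 2, and 122, 77, 190 and 34 without the same libraries of PL.

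The library labelled N2 untreated replicate 2 stood apart from the other N2 libraries, with sperm genes high and oocyte and yolk genes low (vit-2 at 557 CPM against 29800 in replicate 1). A wrongly labelled mutant sample is argued against by lip-1 at 11.5 CPM, above the highest PL library at 3.72, and by fbf-1 at 11.3 CPM, above the highest PF library at 3.89. Animals in a molt are argued against by a molt-gene mean log2 CPM of 0.68, under the 3.94 of the highest other N2 library. The test cannot decide on larvae between molts, in which molt genes need not be high. Males in the sample remain a candidate explanation: 7 of 7 male somatic genes measured were higher in it than in the other 51 libraries, with clec-219 at 707 CPM (next 5.21), clec-207 at 270 (next 2.75) and swm-1 at 51.2 (next 39.6).

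Oocyte genes were higher in PL libraries at 18 h, by a median log2 fold change of 2.44 in DMSO against untreated. N2 animals or RNA mixed into these libraries is argued against by lip-1, which reached at most 0.173 of the level that the N2 share needed for their rme-2 would bring. U0126 in the DMSO animals is argued against by E02C12.6, at 1.1 times the highest untreated PL library, and cyp-35A4, at 0.0856 CPM against 356 or more with the drug. Age of the animals and hours in liquid medium cannot be told apart for the 2.44, because no untreated PL libraries of the later age are among the groups. A biological rise with age in this genotype stays open, untested.

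Somatic lists were lower with U0126 in N2 at 18 h, and a larger germline share would lower all somatic genes alike. The gap between 21 neuron and 16 intestine genes (two-sided permutation test, p = 0.0326, 100000 resamples) does not decide it, since that pair of lists was picked after their medians were seen and embryos in the DMSO animals would make the gap too. A candidate explanation is embryos or larvae held by DMSO animals: the neuron list was 1.65 log2 CPM higher in the lowest N2 DMSO 18 h library than in the highest earlier N2 DMSO library, against -0.41 in PL. The embryonic list had a gap of 0.31 in N2 and -0.11 in PL, and the highest U0126 18 h library of N2 had a neuron mean of 3.16. The intestine list was at 7.36 and 7.41 in N2 DMSO at 18 h, against 7.29 in the highest earlier N2 DMSO library. In N2 with U0126 it was at 6.78 and 6.77 at 6 h and at 6.15 and 6.20 at 18 h. For the intestine list these values argue against embryos or larvae in the DMSO animals as the whole account. Molt-gene means were 3.55 and 3.94 in N2 DMSO at 18 h and 3.59 and 3.86 at 6 h, against 1.87 and 1.93 in U0126 at 18 h. A direct effect of the drug on somatic tissue stays open, untested.

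For PF with U0126 over time, 1 of the 8 splits with 1 library per hour in each group, the real one, called as many genes as the real 89 (highest other 0), and 8 splits are too few for a share under 0.05. For PL against PF in DMSO, 1 of 100 splits drawn within each hour, the real one, reached the real 1321 (highest other 0). The count is thus tied to the real labels. The splits cannot tell genotype from anything else that differed between these PL and PF samples. Both were first counted over splits across hours, where the real split was the only 1 of 32 (highest other 17, with 3 further splits that could not be fitted) and of 100 (highest other 394). They were changed because the hour is in the model. For the difference of PL and PF drug responses the real count by edgeR was 0 (842 genes at an unadjusted p under 0.05, 1 by DESeq2), and a count of 0 is reached by any split, here 100 of 100 (highest other 0), so the splits say nothing about it. For U0126 in PL at 1 h, 5 of 10 splits called as many genes as the real 40 (highest other 464), and 10 splits are too few for a share under 0.05. The 4 splits that put both libraries of replicate 3 in the same group called 78 to 464 genes, which points to a structure of the samples: replicates 1 and 2 had molt-gene means of 5.91 or more and the third replicates of 1.56 or less. Their yolk protein genes differed too, at means of 9.92 to 10.93 log2 CPM in replicates 1 and 2 and 14.12 and 13.94 in the third replicates. Among the 4 splits that part all 3 pairs, the real one called 40 and the others 0, 0 and 0 with edgeR. This count of splits was first run on a fit of the 6 libraries alone, where the real split and the other 9 called 0 genes with edgeR (1.49 percent of genes at an unadjusted p under 0.05 in the real one, and 66 genes called by DESeq2 in the full set of libraries), and was changed after that was seen to the fit of 52 libraries.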

How the results depend on the processing

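The fit without N2 untreated replicate 2, the DMSO 2 h comparison, the robust fit, the 6-library fit at 1 h, the crossed pairing and the fit without PL DMSO 1 h replicates 1 and 2 were chosen after seeing the data. Where no cause is named, the cause was not tested. Values are totals of called genes unless stated, and each comparison not named under an alternative was within 1.5 times its count there.

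Leaving N2 untreated replicate 2 out of the fit, which lowers the pooled spread, gave 926 for PL against PF untreated, 11, 178 and 718 for U0126 in N2 at 1, 2 and 6 h, 62, 250, 340, 456 and 4733 for U0126 in PL at 1, 2, 4, 6 and 18 h, 44 and 1500 for the PL minus N2 drug response at 6 and 18 h, and 1623 and 6814 for PL in DMSO at 1 and 18 h against untreated. It also gave 10764 and 10227 for PL and PF against N2 untreated, and 539 for N2 in DMSO at 1 h against untreated.

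PL against N2 in DMSO at 2 h, with all 52 libraries in the fit, gave 10887. PL against PF in DMSO without PL DMSO 1 h replicates 1 and 2, whose molt, sperm and oocyte genes stood apart, gave 2080, with fog-1 at -0.66 (adjusted p = 0.00281).

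Relative log expression size factors moved 1 count by over 1.5 times, the PL minus N2 response at 18 h (518). With no filter on low counts, the totals were 11 and 134 (N2 at 1 and 6 h), 816 (PL at 18 h), 331 (PF drug), 3 and 15 (PL minus N2 at 1 and 18 h), and 338 and 2323 (PL DMSO against untreated at 1 and 18 h). DESeq2 gave 361 (PL against PF untreated), 53 and 454 (N2 at 1 and 6 h), 66 and 62 (PL at 1 and 6 h), 177 (PF drug), 39, 29, 136 and 1050 (PL minus N2 at 1, 2, 6 and 18 h), 1 (PL minus PF drug), 2575 (PL against PF in DMSO) and 994 (PL DMSO against untreated at 1 h). The robust fit gave 47 for the PF drug.

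With fewer libraries in the fit, edgeR called 0 genes in each untreated genotype comparison with only the 6 untreated libraries (511, 2117 and 2002 at an unadjusted p under 0.05) and 0 in PL at 1 h with its 6 libraries alone (1.49 percent of genes at an unadjusted p under 0.05, and 66 called by DESeq2 with more libraries). Few residual degrees of freedom are left there, and whether that or the spread of these libraries gave the 0 counts was not tested. Fits of the genotypes compared gave 1, 56 and 92 (N2 at 1, 2 and 6 h), 91 and 4281 (PL at 6 and 18 h), 185 (PL minus N2 at 18 h), 201 and 3180 (N2 DMSO against untreated at 1 and 18 h), and 1046 and 5957 (PL DMSO against untreated at 1 and 18 h). With all 52 libraries in the fit, PF drug gave 321 and PL minus PF drug 2. Without the third replicates, PL at 1 h gave 24 and PL DMSO at 1 h against untreated 2136.

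With a replicate block, the counts were 653 (PL against PF untreated), 405 (N2 at 6 h), 19 and 877 (PL minus N2 at 6 and 18 h) and 2589 (PL DMSO at 1 h against untreated), and the block moved no other count by over 1.5 times. In N2 at 6 h same-numbered libraries correlated at -0.166, and the block with crossed pairing gave 391. In these comparisons the libraries are known to share only a number. At the other hours of N2, 1, 2 and 18 h, same-numbered libraries correlated at 0.474, 0.525 and -0.029. In PL at 2, 4, 6 and 18 h they correlated at 0.419, 0.239, 0.095 and 0.528. With 2 pairs the crossed value is the same with its sign reversed, so shared handling at those hours is neither shown nor excluded.

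Leaving out 1 library, with the lone sample assumed to vary like the other groups, gave lowest and highest totals of 16 and 43 (PL against PF untreated), 4230 and 10764 (PL against N2), 4048 and 10227 (PF against N2), 1 and 4, 63 and 99, 75 and 95, 4705 and 5335 (N2 at 1, 2, 6 and 18 h), 26 and 53, 66 and 390, 112 and 149, 13 and 16, 451 and 1286 (PL at 1, 2, 4, 6 and 18 h), 0 and 4, 0 and 134, 1 and 6, 27 and 190 (PL minus N2 at 1, 2, 6 and 18 h), 539 and 10689, 3855 and 9539 (N2 DMSO against untreated at 1 and 18 h), and 88 and 1394, 1219 and 2139 (PL DMSO against untreated at 1 and 18 h). Leaving out 1 pair of PF libraries gave 22 and 173 (PF drug), 0 and 1 (PL minus PF drug), and 428 and 929 (PL against PF in DMSO). For the list tests, 12 passed with an estimated correlation and 115 with fry, against 227.

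Single genes changed direction in 11 cases. Without N2 untreated replicate 1, the log2 fold change in PL against N2 was 0.2 for tra-2, 0.47 for gld-1, 0.1 for mpk-1 and 0.41 for rme-2, and in PF against N2 0.35 for tra-2 and 0.03 for mpk-1, since replicate 2 alone then stands for N2. Without replicate 2 these were -1.74 for tra-2, -1.73 for mpk-1 and -4.3 for rme-2 in PL, -3.08 for gld-1 in PL vs N2 untreated, and -1.58 and -1.79 in PF. For fog-3 in N2 DMSO vs untreated 18 h, the value was 0.86 without N2 untreated replicate 2 and -5.34 without replicate 1. In DMSO at 2 h, PL against N2 was 1.1 for F09C6.10, 0.2 for clec-161, 1.07 for try-8 and 1.03 for C16C8.7. Median depth was lowest in PF, at 7.305 (counts in units of 1e6) against 13.58 in PL and 16.71 in N2. The lowest library was at 5.37 in PF and 5.66 in PL.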

Other observations

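Fat, immune and hypoxia genes also moved in N2 at 18 h of U0126, with TMM first and relative log expression scaling second. Intestine, muscle and neuron lists fell in the same comparison. Whether these genes moved apart from that fall, for which a larger germline share and embryos in the DMSO animals were weighed above, was not tested. Of 27 genes of fasting and fatty acid metabolism 14 and 9 fell and 2 and 2 rose (medians -0.93 and -0.47), including the desaturases fat-2 (-1.39) and fat-3 (-1.37) and the dehydrogenase acdh-1 (-1.41), with adjusted p = 0.311 with an estimated correlation. Of 32 immunity genes 12 and 6 fell, the lysozyme lys-7 at -3.47 and the saposin-like spp-1 at -1.73. Of the hypoxia list cysl-1 (-2.17), ldh-1 (-1.45) and egl-9 (-1.19) fell. Of the RAS-ERK list 8 and 15 of 27 rose and 10 and 4 fell, where the direction of the split flips with the scaling, and soc-2 (-1.33), let-23, the EGF receptor (-1.03), and lin-25 (-1.41) fell with TMM. Of the immediate-early list, lin-39 (-1.69), jun-1 (-0.94) and egrh-1 (-0.89) fell with TMM.

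In PL in DMSO at 18 h against untreated, 9 of 27 RAS-ERK genes rose with TMM and 8 with the other scaling, including ksr-2 (1.29), a scaffold of the germline pathway, lin-25 (1.29) and eor-1 (1.03), with adjusted p = 0.515 with an estimated correlation. Ribosomal protein genes fell for 36 of 77 with TMM and 56 with the other scaling, rpl-11.2 at -1.25. Fat-metabolism genes rose for 10 of 27 and fell for 3, with lipl-4 at 3.19 and fat-1 at 1.27. Histone genes his-59 (-2.93) and his-60 (-3.31) fell. The yolk protein genes had medians of 1.39 and 1.24, and 0 of 6 passed with edgeR.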
